A study of Caenorhabditis elegans with 12 samples.

How the data were processed

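Whole Caenorhabditis elegans embryos at the 3-fold stage were measured on 12 Affymetrix arrays, 4 of each of 3 genotypes. The deposited values are on a log2 scale, and the submitters' processing notes name RMA without a version. Values ran from 2.78 to 14.71, and the median of an array lay between 6.20 and 6.36. The number of arrays limits the precision. The labels do not say that replicates came from separate cultures, so a p-value here measures only the spread between these samples.

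All 12 columns were mapped to a label and 0 were left unmapped. Arrays 1 and 2 of the daf-19 daf-12 double mutant were identical in all 22625 probe sets, so they were counted as 1 array. This left 3 arrays of the double mutant, 4 of the daf-12 mutant and 4 of the wild type, 11 in all.

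The 77 control probe sets were left out and 22548 were tested. The annotation gave 20766 probe sets 1 gene name, 887 several and 895 none. A gene table of assembly WBcel235, used for names alone, held 20701 of the 20766, and it changed 0 symbols. The named probe sets covered 17118 genes, of which 2981 had more than 1 probe set.

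Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over the 11 arrays, with no block. Tests were two-sided and adjusted by Benjamini-Hochberg over all tested probe sets, and a probe set was called at an adjusted p under 0.05. The 3 comparisons, the 34 gene lists, the rule for naming genes, the tests and most alternatives were chosen before the data were examined. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Calls within a list were counted over all probe sets and adjusted over the list alone. Where a gene had several probe sets, the one with the highest mean over the arrays stood for it. The overlap of calls was set against unchanged simulated groups, with no sets of arrays or pairing, in 100 simulations.

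Named genes were daf-19, daf-12, dyf-18 and mks-6, up to 4 called members of a list with the largest changes, and the called genes with the largest changes whose arrays did not overlap between groups. In the comparisons with the daf-12 mutant as a member, up to 12 were taken in each direction, and up to 6 in the comparison of the double mutant with wild type. Probe sets with several gene names or none were not named by this rule. The gene dyf-11 and R11A5.3 were chosen after their values were seen. Other members of a list named beside a count adjusted over the list alone were also chosen after their values were seen, and so were ZC132.11, rab-28, F09E5.12 and clip-1.

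Poly-A spike-in controls, 24 probe sets, separated replicates 1 and 2 from replicates 3 and 4 in every group. The labels give no batch. A block for these 2 sets of arrays, fits of either set alone, and a fit of all 12 arrays as separate samples were therefore alternatives chosen after seeing the data. The genes named with this block were taken by the same rule. The pairing of replicate numbers was checked by correlating deviations of probe sets from their group means between arrays of the same number. The correlation was 0.22 to 0.29 between the double mutant and the daf-12 mutant and 0.33 to 0.49 between the double mutant and wild type. Between the daf-12 mutant and wild type it ran from -0.03 to 0.67. Double mutant array 1-2 entered under both of its numbers, so the double mutant gave 3 different arrays to this check. An array's own number was its best match in 2 of 4 cases in each of the 3 comparisons, and array 1-2 could have only 1 of its 2 numbers as its best. The replicate numbers are nested in the 2 sets of arrays, so a correlation at the same number also holds the shift between the sets. Between the daf-12 mutant and wild type, daf-12 array 2 correlated at -0.03 with its own number and up to 0.65 with another. For daf-12 array 3 these were 0.03 and 0.68. These values do not settle whether equal numbers mark pairs, so the fit with a replicate block is given beside the fit without one.

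Recovery was tested on simulated data, with 100 changed probe sets of each size added to unchanged values. The fit without a block called 29% of changes of 1 on the log2 scale and 82% of changes of 2 for the double mutant against the daf-12 mutant. The shares were 25% and 80% for the double mutant against wild type, and 31% and 81% for the daf-12 mutant against wild type. With the set of arrays as a block they were 45% and 89%, 49% and 92%, and 53% and 91%. The simulated values held a shift between the sets that was equal in all groups, as this block assumes, so they favour it. False calls among unchanged probe sets numbered 3, 3 and 0 without a block and 9, 14 and 1 with it. A planned test of X-box motifs upstream of called genes was not run, since no genome sequence was used here.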

Results

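Gene expression was measured in whole worm embryos at the 3-fold stage, late in embryonic elongation, in a daf-19(m86) daf-12(sa204) double mutant, a daf-12(sa204) mutant and the wild type N2. DAF-19 is an RFX transcription factor of genes for sensory cilia, and DAF-12 is a nuclear hormone receptor. There were 3 different arrays of the double mutant, because 2 of its 4 columns were identical, and 4 arrays of each other group. The double mutant column that stands for numbers 1 and 2 is called array 1-2 here.

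The arrays fell into 2 sets that the labels do not mention. The 24 poly-A spike-in probe sets averaged 4.16 to 4.32 on replicates 1 and 2 of all groups and 7.16 to 10.21 on replicates 3 and 4. Deviations from the group mean correlated across probe sets with a median r of 0.303 between arrays of different groups in the same set, and -0.309 between sets. Probe sets are not independent replicates.

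**Figure D1:**
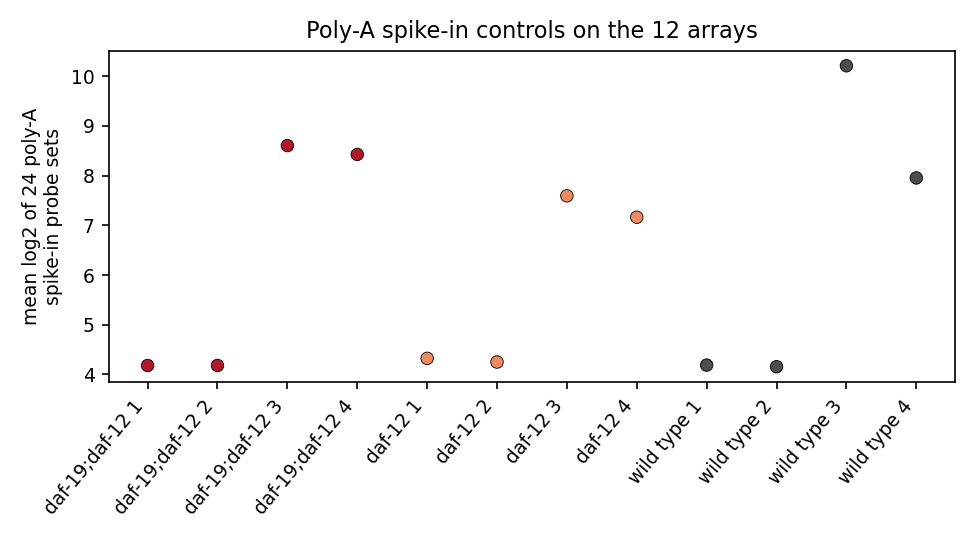
Mean log2 value (y axis) of the 24 poly-A spike-in probe sets on each of the 12 deposited arrays (x axis), coloured by group. Replicates 1 and 2 lie at 4.16 to 4.32 in each group and replicates 3 and 4 at 7.16 to 10.21.

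The transcript of daf-19 itself was lower in the double mutant, at 8.52 ± 0.32 (SD, n = 3) on the log2 scale against 9.97 ± 0.15 (n = 4) in the daf-12 mutant and 10.14 ± 0.26 (n = 4) in wild type. The log2 change was -1.45 ± 0.20 (SE) against the daf-12 mutant (limma adjusted p = 0.0281) and -1.62 ± 0.20 against wild type (adjusted p = 0.00891). With a replicate block the first had an adjusted p of 0.0553, which ended its call, and the second 0.0268. The other daf-19 probe set gave -1.77 and -1.93. Array means of daf-12 were 8.57 ± 0.49, 8.75 ± 0.18 and 8.80 ± 0.52 in the same order, and it was called in no comparison.

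The comparison of the double mutant with the daf-12 mutant asks which genes depend on DAF-19, since the genotypes differ by daf-19(m86). Genes of the cilium were lower in the double mutant. The transition zone gene tctn-1 (tectonic) fell by 2.66 ± 0.20 (SE, n = 3 and 4) on the log2 scale (adjusted p = 0.00067), and dylt-2, a dynein light chain of ciliary transport, fell by 2.81 ± 0.36 (adjusted p = 0.0235). The transition zone gene mksr-2 was 4.61-fold lower, and the log2 changes were -1.69 in tmem-107, of the same zone, -1.51 in the BBSome gene bbs-5, -1.96 in xbx-3 and -1.40 in xbx-9. The largest falls among single genes were in Y41E3.5, at -3.49 ± 0.40 (adjusted p = 0.0107), and R102.2, at -3.36 ± 0.34 (adjusted p = 0.00593). The gene oac-59 was lower at 1 probe set, at -2.31 (adjusted p = 0.0248), while the brighter probe set that stands for it gave -2.27 (adjusted p = 0.0616).

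limma called 13 of 22548 probe sets lower in the double mutant, for 11 genes and 1 probe set of several genes (R01H2.8 and tmem-17), and 0 higher. At an unadjusted p under 0.05, 538 were lower and 571 higher. Blocking on the set of arrays gave 41 lower, the same 13 among them, and 7 higher. With a replicate block 12 were lower and 2 higher, 7 of them among the 13; tctn-1, R102.2, Y41E3.5, mksr-2, xbx-3 and bbs-5 kept their calls, while dylt-2 (adjusted p = 0.0505), tmem-107 (0.0864) and xbx-9 (0.0936) did not. Within replicates 1 and 2 and within replicates 3 and 4, tctn-1 differed by -2.30 and -2.80, and Y41E3.5 by -3.52 and -3.55. The count of lower probe sets was 26 without double mutant array 1-2, 1 without array 3 and 1 without array 4. It was 23, 6, 3 and 3 without daf-12 arrays 1, 2, 3 and 4 and 6 without wild type array 4. The count of higher ones was 48 without double mutant array 1-2. Of the 13, tctn-1 was called in 11 of 11 fits that left out 1 array.

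**Figure D2:**
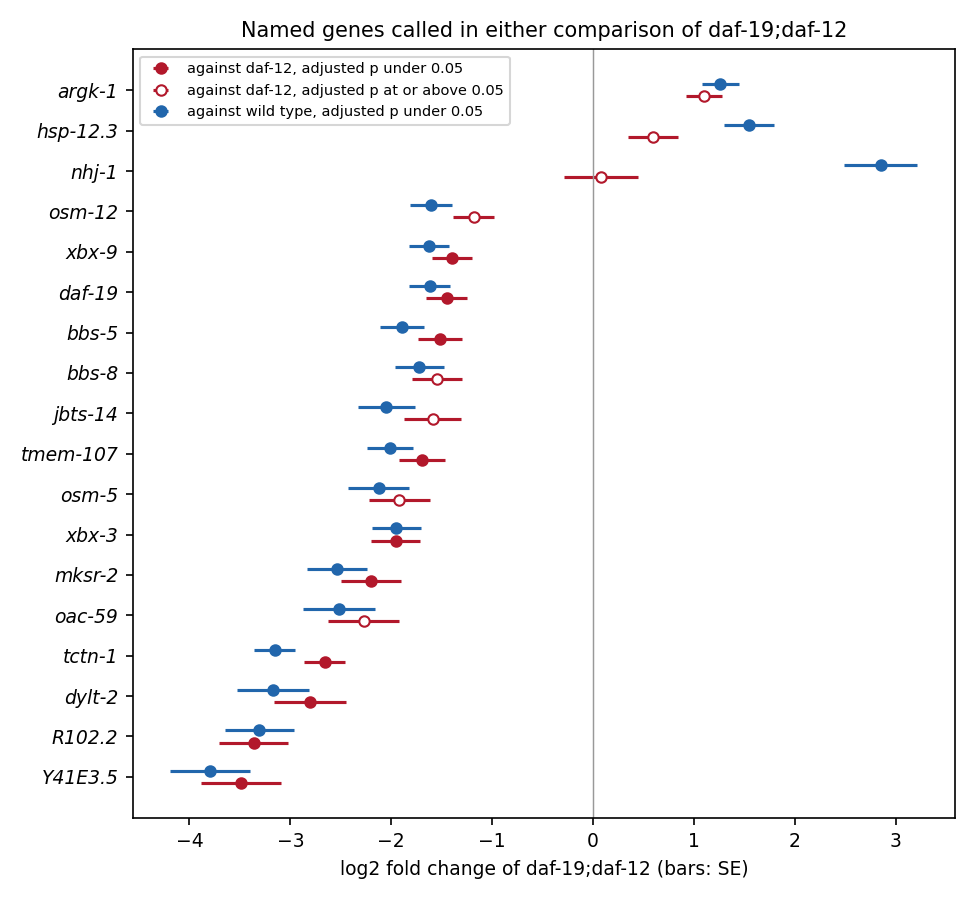
Log2 fold change (x axis) of the double mutant against the daf-12 mutant (red) and against wild type (blue) for the named genes (y axis) called in either comparison, with bars of 1 SE and filled points where the adjusted p was under 0.05. The change in tctn-1 was -2.66 and -3.15, and that in nhj-1 was 0.08 and 2.85.

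Further genes were called with the set of arrays as a block, and unless stated the log2 changes here are from that fit. The intraflagellar transport genes osm-5 (adjusted p = 0.00877) and ift-139 (-1.77, adjusted p = 0.0477) were lower, though another ift-139 probe set gave 0.06 without the block and another osm-5 probe set -1.16. The genes xbx-4, jbts-14 and bbs-8 changed by -1.71, -1.65 and -1.60, and another jbts-14 probe set gave -1.09 without the block. Also lower were F55A4.3 (-3.07), ddn-2 (-2.91), C33A12.4 (-2.90), K07C11.10 (-2.59), ptp-8 (-2.28) and the hedgehog-related gene wrt-4 (-0.97). Heat shock genes were higher, hsp-16.2 by 2.00 ± 0.20 (SE, adjusted p = 0.00235) and hsp-70 by 2.03 ± 0.33 (adjusted p = 0.045), as were R11A5.3 by 1.87 and the arginine kinase gene argk-1 by 1.08. Without a block none of these genes was called, with adjusted p of 0.254 for hsp-16.2, 0.682 for hsp-70 and 0.0666 for argk-1. The replicate block called F55A4.3, C33A12.4, ptp-8, hsp-16.2 and R11A5.3 (adjusted p from 0.00789 to 0.0316). It did not call osm-5 (0.0505), ift-139 (0.202), xbx-4 (0.0954), jbts-14 (0.147), bbs-8 (0.0759), ddn-2 (0.147), K07C11.10 (0.0505), wrt-4 (0.109), hsp-70 (0.1) or argk-1 (0.136). Double mutant and daf-12 arrays overlapped in hsp-70 and R11A5.3. Of the ciliary genes that were of interest before the data were examined, mks-6 differed without the block by -2.32 ± 0.39 (adjusted p = 0.068) and dyf-18, a cyclin-dependent kinase-related gene, by -0.93 ± 0.32 (adjusted p = 0.837), and neither was called with either block.

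Ciliary genes moved together. In the 6 lists of intraflagellar transport (IFT), BBSome, transition zone and other ciliary genes, 59 of 67 measured genes were below 0, with a median log2 change of -1.02. Of the 67, 6 were called lower and 61 were not called; 39 were called lower when adjusted over the list alone. In 44 of them all double mutant arrays lay below all daf-12 arrays, which chance gives for 2.86% of genes in that direction, and which held for 3.23% of all genes. Calls numbered 12 with the set of arrays as a block and 4 with a replicate block. The 7 BBSome genes had a median of -1.42 (camera adjusted p = 3.3e-17; adjusted p = 0.00959 with an estimated correlation), and 7 of the 7 were called when adjusted over the list alone. The 14 transition zone genes had a median of -1.38, with 3 called and 10 called when adjusted over the list alone (adjusted p = 8.7e-23, and adjusted p = 0.0301 with an estimated correlation). The 20 other ciliary genes had a median of -0.40 (adjusted p = 3.9e-08, and adjusted p = 0.0447 with an estimated correlation). With both the set of arrays as a block and an estimated correlation, the BBSome list held (adjusted p = 0.0295), while the transition zone and other ciliary lists did not (adjusted p = 0.0745 each).

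The IFT lists lost their calls with an estimated correlation. The 13 genes of complex B had a median of -1.39, with 0 called by limma and 9 called when adjusted over the list alone (adjusted p = 6.1e-14, but adjusted p = 0.0747 with an estimated correlation). The 6 of complex A had a median of -1.17 (adjusted p = 1.1e-07, but adjusted p = 0.0747 with an estimated correlation). The 7 motor genes had a median of -0.52 (adjusted p = 8.2e-06, but adjusted p = 0.0787 with an estimated correlation). Within replicates 1 and 2 and within replicates 3 and 4 the medians were -0.65 and -1.94 for complex B, -0.57 and -1.72 for complex A, -0.67 and -1.68 for the BBSome, -0.62 and -1.80 for the transition zone, -0.31 and -0.91 for the motors, and -0.19 and -0.53 for the other ciliary genes. In complex B the daf-12 arrays 3 and 4 had mean deviations from each gene's own mean of 0.98 and 1.29, its arrays 1 and 2 -0.49 and -0.23, and the wild type arrays -0.08 to 0.60. Also in complex B, dyf-11 went the other way, with 0.61 ± 0.60. The number of ciliary genes called was 1 without double mutant array 3 or 4, 12 without daf-12 array 1, 2 without its array 2, 1 without its array 3 or 4, and 3 without wild type array 4.

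**Figure D3:**
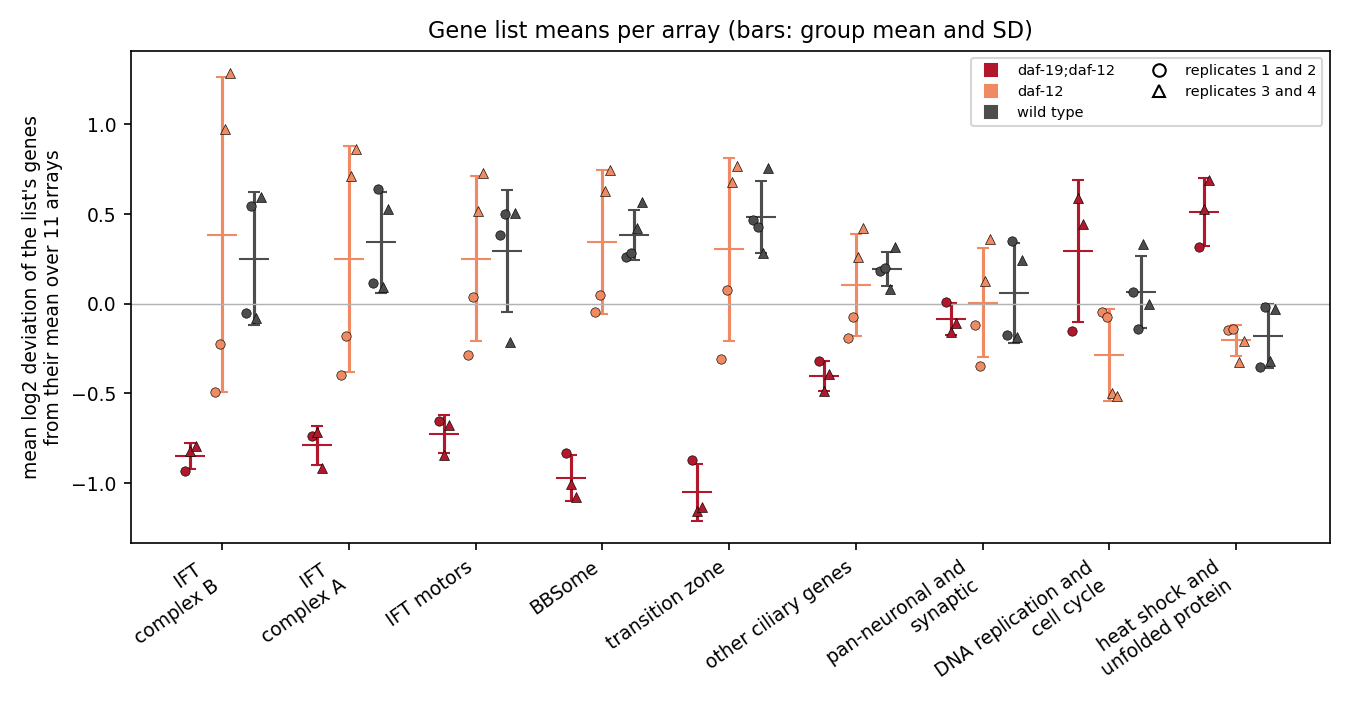
Mean log2 deviation of each list's genes from their mean over 11 arrays (y axis) for 9 lists (x axis), with 1 point per array and bars for the group mean and SD. In the transition zone list the double mutant averaged -1.05, the daf-12 mutant 0.30 and wild type 0.48.

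Outside the ciliary lists, the 12 measured heat shock and unfolded protein genes had a median of 0.40, with 0.20 within replicates 1 and 2 and 0.76 within replicates 3 and 4 (adjusted p = 3.6e-06, and adjusted p = 0.0306 with an estimated correlation). limma called 0 of them over all probe sets, and 4 were called higher when adjusted over the list alone: hsp-16.2 (2.19), hsp-70 (2.29), hsp-16.41 (1.68) and hsp-4 (1.41), which encodes an endoplasmic reticulum chaperone. Blocking on the set of arrays gave an adjusted p = 0.113 with an estimated correlation, and 2 members were called. The 24 DNA replication and cell cycle genes had a median of 0.62 (adjusted p = 4.1e-15, but adjusted p = 0.0747 with an estimated correlation), and 7 were called higher when adjusted over the list alone, among them the cyclin genes cyb-1 (1.25) and cye-1 (0.73). Their median was -0.08 within replicates 1 and 2 and 0.98 within replicates 3 and 4. The 26 histone genes had a median of 0.35, with -0.28 and 0.81 within the sets (adjusted p = 3.6e-09, but adjusted p = 0.252 with an estimated correlation).

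Further lists passed with the preset correlation alone. Detoxification genes (177, median -0.17) had an adjusted p of 1.3e-05, nuclear hormone receptors (254, -0.12) 0.000851 and hedgehog-related genes (80, -0.16) 0.000181, each with an adjusted p = 0.0747 with an estimated correlation. Ciliary tubulin and male-type ciliary genes (13, -0.17) had an adjusted p of 0.00317, but adjusted p = 0.0747 with an estimated correlation. Receptor guanylyl cyclases (32, -0.18), touch receptor neuron genes (11, -0.31), neuropeptides (83, -0.12), collagens (128, -0.15) and major sperm proteins (23, 0.30) had adjusted p of 0.00386, 0.00416, 0.0413, 0.0026 and 0.0026. With an estimated correlation their adjusted p = 0.122, 0.426, 0.895, 0.895 and 0.726. The major sperm protein list turned direction, with medians of -0.54 within replicates 1 and 2 and 0.94 within replicates 3 and 4, as did the receptor guanylyl cyclases, with 0.04 and -0.17. The same medians were -0.22 and -0.46 for touch receptor neuron genes, -0.07 and -0.21 for neuropeptides, -0.28 and -0.14 for collagens, -0.09 and -0.17 for detoxification genes, and -0.04 and -0.16 for nuclear hormone receptors. The 26 pan-neuronal and synaptic genes did not pass (median -0.06, adjusted p = 0.577), nor did sensory signal transduction genes (21, median -0.32, adjusted p = 0.293), chemoreceptors (1275, -0.04, 0.381) or amphid glia genes (14, -0.09, 0.734). The lists of insulin-like peptides, dauer signalling, body wall muscle, pharynx, intestine, furrow collagens, early embryo, germline, ribosomal proteins, oxidative and metal stress, C-type lectins and F-box genes had adjusted p from 0.0712 to 0.914.

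Ciliary genes were also lower in the double mutant than in wild type. The gene tctn-1 fell by 3.15 ± 0.20 (SE, n = 3 and 4; adjusted p = 0.000105), and log2 changes were -3.79 ± 0.40 in Y41E3.5 (adjusted p = 0.00459), -3.31 ± 0.34 in R102.2 (adjusted p = 0.00459), -3.17 ± 0.36 in dylt-2 (adjusted p = 0.00675) and -2.54 ± 0.30 in mksr-2 (adjusted p = 0.00774). Also lower were the IFT gene osm-5 (-2.12), the transition zone gene jbts-14 (-2.05), the BBSome genes bbs-8 and osm-12 (-1.72 and -1.60), and oac-59 (-2.52). Another probe set gave -0.96 for osm-5 and -1.43 for jbts-14, neither called (limma adjusted p = 0.831 and 0.125). Higher were nhj-1, a gene of DNA end joining, by 2.85 ± 0.36 (adjusted p = 0.0106), the small heat shock gene hsp-12.3 by 1.55 ± 0.25 (adjusted p = 0.0442) and argk-1 by 1.26 ± 0.18 (adjusted p = 0.0191). The gene nhj-1 differed between the double and the daf-12 mutant by 0.08 ± 0.36. For hsp-12.3 that difference was 0.59 ± 0.25 with overlapping arrays (limma adjusted p = 0.967), and the daf-12 mutant lay above wild type by 0.96, not called.

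limma called 23 probe sets lower, for 19 genes and 2 probe sets of several genes, and 3 higher. Genes called lower that the rule did not name were ZC132.11 (-1.89), rab-28 (-1.55), F09E5.12 (-1.43) and clip-1 (-1.39). Blocking on the set of arrays gave 44 lower and 7 higher, the 26 among them, and a replicate block gave 27 and 5, of which 21 were shared. The replicate block ended the calls of osm-12 (adjusted p = 0.055) and argk-1 (adjusted p = 0.0551), and also those of ZC132.11 and clip-1. The count of lower probe sets was 5 without double mutant array 3, 2 without its array 4 and 14 without wild type array 4. The count of higher ones was 14 without double mutant array 1-2, 0 without its array 3 or 4, and 1 without wild type array 1, 3 or 4.

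Of the 67 ciliary genes, 65 were below 0 against wild type, with a median of -1.02. There were 10 called lower and 57 not called, while 39 were called lower and 0 higher when adjusted over the list alone. In 39 of the 67 the groups did not overlap on the lower side, where chance gives 2.86%. In 1, dyf-11 (1.37 ± 0.60), they did not overlap on the higher side. Calls numbered 16 with the set of arrays as a block and 11 with a replicate block; the count was 2 without double mutant array 3 and 1 without its array 4. The BBSome (median -1.60, adjusted p = 4.5e-18), transition zone (-1.46, 1.6e-28) and other ciliary lists (-0.47, 4.1e-11) held with an estimated correlation, at adjusted p of 0.0081, 0.015 and 0.0218. IFT complex B (-1.22, 1.6e-11), complex A (-1.17, 6.4e-09) and the motors (-0.51, 7.9e-07) had adjusted p = 0.134, 0.0729 and 0.0744 with an estimated correlation. The medians within replicates 1 and 2 and within replicates 3 and 4 were -1.25 and -1.26 for complex B, -1.29 and -1.55 for the transition zone, -1.03 and -1.64 for the BBSome, and -0.81 and -0.56 for the motors.

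The heat shock list was higher than in wild type too (median 0.34, adjusted p = 5.9e-06, and adjusted p = 0.025 with an estimated correlation), with 0.38 and 0.54 within the sets of arrays and 4 genes called higher when adjusted over the list alone. Hedgehog-related and patched-related genes were lower (median -0.21, adjusted p = 6.8e-06, and adjusted p = 0.0466 with an estimated correlation), with 0 called by limma and 1 called lower when adjusted over the list alone. With the set of arrays as a block these lists had adjusted p = 0.0787 and 0.0744 with an estimated correlation, and wrt-6 of the second fell by 1.16 ± 0.15 (adjusted p = 0.00607, and 0.0547 with a replicate block). The ciliary tubulin (-0.25), chemoreceptor (-0.12), intestine (0.17), DNA replication (0.23), histone (0.13) and oxidative and metal stress (0.18) lists passed at adjusted p of 0.00587, 0.000853, 0.0229, 0.000501, 0.00232 and 0.0185. With an estimated correlation their adjusted p = 0.0729, 0.973, 0.425, 0.567, 0.697 and 0.466. Direction turned within replicates 1 and 2 for the DNA replication (median -0.11, against 0.32 within replicates 3 and 4), histone (-0.10 against 0.24) and chemoreceptor lists (0.03 against -0.14). The same medians were -0.11 and -0.23 for hedgehog-related genes, -0.12 and -0.26 for the ciliary tubulin list, 0.00 and 0.14 for the intestine list, and 0.20 and 0.11 for oxidative and metal stress.

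The 13 probe sets lower than in the daf-12 mutant were all among the 23 lower than in wild type. Independent lists of these sizes would share 0.0133, and unchanged simulated groups with the same shared arrays shared at most 1 in 100 simulations. The 2 comparisons share the double mutant arrays, and the simulated groups held no change. Neither value therefore gives the overlap expected once the double mutant differs from either group. The simulation held neither the 2 sets of arrays nor any pairing, and regrouping the real arrays gave up to 188 shared probe sets. No probe set was higher than in both groups without a block (0 by limma, of 571 and 436 at an unadjusted p under 0.05). Blocking on the set of arrays gave 36 lower and 4 higher than in both, and a replicate block 11 and 2. The shared count of lower probe sets was 1 without double mutant array 3 or 4, 21, 5, 3 and 3 without daf-12 arrays 1 to 4, and 6 without wild type array 4. That of higher ones was 12 without double mutant array 1-2.

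The comparison of the daf-12 mutant with wild type asks what the daf-12 mutation does on its own. The gene nhj-1 was higher in the daf-12 mutant by 2.77 ± 0.34 (SE, n = 4 and 4; adjusted p = 0.0382), at 9.83 ± 0.41 (SD) against 7.06 ± 0.69, and at 9.91 ± 0.43 in the double mutant. Ciliary genes were not called: of the 67, 41 were below 0, with a median of -0.09. Detoxification genes were higher as a list (177 genes, median 0.23, adjusted p = 2.6e-13, and adjusted p = 0.0423 with an estimated correlation), with medians of 0.22 within replicates 1 and 2 and 0.17 within replicates 3 and 4, and 0 of them called by limma. In 16 of these genes all daf-12 arrays lay above all wild type arrays, which chance gives for 1.43% in that direction. The list had an adjusted p = 0.116 with an estimated correlation when the set of arrays was a block.

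limma called 3 probe sets higher, nhj-1 and 2 of several genes, and 0 lower, with 435 higher and 246 lower at an unadjusted p under 0.05. With the set of arrays as a block 5 were higher, C06E4.3 (1.63, adjusted p = 0.0478, and 0.233 with a replicate block) among them, and with a replicate block 2. The count was 2 without daf-12 array 2, 1 without wild type array 4, and 0 without any other single array. Oxidative and metal stress genes (median 0.53, adjusted p = 1e-06) had an adjusted p = 0.229 with an estimated correlation, with medians of 0.61 and 0.06 within the sets. Nuclear hormone receptors (0.07), collagens (0.11), neuropeptides (0.11) and touch receptor neuron genes (0.23) passed upwards, at adjusted p of 0.00234, 4.1e-05, 0.00331 and 0.0121. With an estimated correlation their adjusted p = 0.279, 0.882, 0.882 and 0.882. DNA replication (-0.30), major sperm protein (-0.42), histone (-0.21), ribosomal protein (-0.08), transition zone (-0.29), chemoreceptor (-0.07) and early embryo lists (-0.14) passed downwards, at adjusted p of 6.8e-08, 2.3e-06, 0.00107, 0.00166, 0.0116, 0.0116 and 0.0404. With an estimated correlation their adjusted p = 0.68 for the first and 0.882 for the others. Medians within replicates 1 and 2 and within replicates 3 and 4 had opposite signs for major sperm proteins (0.13 and -1.06), histones (0.11 and -0.57), early embryo genes (0.09 and -0.45), chemoreceptors (0.05 and -0.20) and ribosomal proteins (0.00 and -0.13). They also did for the transition zone (-0.57 and 0.09), collagens (0.43 and -0.20), neuropeptides (0.33 and -0.02) and touch receptor neuron genes (-0.04 and 0.33). DNA replication genes had -0.07 and -0.74, and nuclear hormone receptors 0.02 and 0.14.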

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

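The tests of explanations for the 3 patterns, the splits with the set of arrays as a block and the splits of the ciliary mean were chosen only after the results were seen, and the bounds of the embryo stage, neuron and stress tests were tightened after their values were seen. Dixon's test, which chance passes in about 1 of 20 groups, was applied to 148 group values, and 6 passed where 7.4 were expected by chance. Within the daf-12 mutant, array 3 stood apart for daf-12 (0.937, at 8.48 against 8.83 to 8.85) and for the furrow collagen list (0.877), and array 1 for the F-box list (0.849). Within the wild type, array 3 stood apart for daf-19 (0.949, at 9.75 against 10.25 to 10.28), jbts-14 (0.848) and the IFT motor list (0.830). The wild type array 3 also had the highest spike-in mean, 10.21.

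The lower ciliary genes of the double mutant were weighed first. A block did not decide on a shift between the 2 sets of arrays. The median of the ciliary genes was -1.08 with the block and -1.02 without it. The groups are nearly balanced over the sets, so the block could move this median little. With a single shift for all groups in the model, the ciliary lists were higher in replicates 3 and 4 (medians 0.15 to 0.47). Array means of the transition zone list did not rise in all groups. In that list daf-12 arrays 1 to 4 had -0.31, 0.07, 0.68 and 0.77. Double mutant arrays 1-2, 3 and 4 had -0.87, -1.15 and -1.13, and wild type arrays 1 to 4 had 0.47, 0.43, 0.28 and 0.76. The medians therefore do not decide on a shift equal in all groups. A shift that differs between groups stays open. The complex B median was -0.65 within replicates 1 and 2 and -1.94 within replicates 3 and 4. Fewer neurons as a whole were argued against by the pan-neuronal list, whose mean differed by -0.089 ± 0.160 (SE) from the daf-12 mutant where the ciliary genes differed by -1.01 ± 0.256, and by -0.143 ± 0.148 from wild type where they differed by -1.06 ± 0.102. An earlier embryo stage of the double mutant stays open: from a line of ciliary mean on DNA replication mean over the other 8 arrays, the double mutant lay at a mean residual of -0.722 (-0.995 to -0.545), but the others reached -0.521 with a residual SD of 0.302. Double mutant arrays 3 and 4 had DNA replication means of 0.588 and 0.447, above the -0.515 to 0.334 of the 8 arrays in the line. Their residuals are therefore extrapolated, and only array 1-2, at -0.154, lay within that range. The loss of DAF-19, which the design names, stays a hypothesis beside these open explanations.

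The higher DNA replication list of the double mutant was weighed next. Within replicates 3 and 4 the daf-12 mutant lay at -0.744 against wild type, and the double mutant at 0.984 against the daf-12 mutant, so the daf-12 arrays 3 and 4 standing apart could account for most of it. Within replicates 1 and 2 the double mutant lay at -0.0778 against the daf-12 mutant, but that set held 1 different array of the double mutant, so an effect of daf-19 in both sets cannot be told apart from none.

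The higher heat shock list of the double mutant was weighed last. In each set of arrays the lowest double mutant mean lay above the highest of the other groups, by 0.336 and 0.554 (log2). The gap of 0.336, within replicates 1 and 2, rests on 1 double mutant array. The gaps argue against a shift between the sets that is equal in all groups. A shift that differs between the groups was not tested. Stress of all kinds stays open: the oxidative and metal stress list differed by -0.221 ± 0.045 (SE) from the daf-12 mutant, where the heat shock list differed by 0.715 ± 0.117, but by 0.253 ± 0.189 from wild type, where the heat shock list differed by 0.690 ± 0.141. Warmer handling of the double mutant embryos would raise the list on each of its arrays, as seen with 0.554 and 0.336, so it cannot be told apart from an effect of the genotype, since handling is not in the labels.

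Other splits of the same arrays were counted for each result. For the double mutant against the daf-12 mutant, 2 of 35 splits called 13 probe sets or more, so chance was not excluded by this count; the other was the split by the set of arrays, with 790. That number, many times the real count, points to a structure of the samples. When the set of arrays was a block the real split called 48 and the highest other 11, and 1 of 35 gave as many, which excludes chance only among splits that ignore the set and number of the arrays. The 8 splits that part all pairs of numbers gave at most 0 other calls without a block and 11 with it, but are too few for a share under 0.05. For 18 lists past the threshold it was 6 of 35 with a highest of 25, which does not exclude chance. For 6 ciliary genes called it was 1 of 35, with 1 as the highest other, which excludes chance among these splits with the same limit. The difference of the ciliary mean, 1.01, was reached by 2 of 35, which does not exclude chance. The highest other, 1.07, came from the split of daf-12 arrays 2, 3 and 4 against the rest.

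For the double mutant against wild type, 3 of 35 splits called 26 or more, so chance was not excluded by this count. The split by the set of arrays gave 1533, and that of double mutant arrays 3 and 4 with wild type array 3 gave 318. When that set was a block the real split gave 51, and 2 of 35 gave as many, the latter split with 1629. These are the 3 arrays with the highest spike-in means, and such counts point to a structure of the samples beyond the 2 sets. For 14 lists it was 13 of 35 with a highest of 23, which does not exclude chance. For 10 ciliary genes called it was 1 of 35 (highest other 1), and for the difference of the ciliary mean, 1.06, it was 1 of 35 (highest other 0.919), which exclude chance among these splits, while the 8 that part all pairs are again too few for a share under 0.05.

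For the daf-12 mutant against wild type, 3 of 35 splits called 3 or more, with 3106 for the split by the set of arrays. With that set as a block, where the real split gave 5, it was 2 of 35, with 3518 for daf-12 arrays 1 and 2 with wild type arrays 1 and 3 against the rest. For 13 lists it was 11 of 35 with a highest of 22. Ciliary genes moved with the structure of these samples too: the split by the set of arrays called 10 of them lower, and that of daf-12 arrays 1 and 2 with wild type arrays 1 and 3 called 22, as many as or more than the 6 and 10 called in the double mutant. None of the 3 excludes chance, and the counts of 3106 and 3518 point to a structure of the samples. For 13 probe sets lower in the double mutant than in both other groups, 2 of 100 drawn splits gave as many. The drawn splits also dealt the remaining arrays at random to the other 2 groups. They therefore do not test the double mutant grouping alone. The share excludes chance only among such splits, which ignore the set and number of the arrays. The highest other, 188, points to a structure of the samples. With the set of arrays as a block 36 were shared.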

How the results depend on the processing

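The alternatives with the set of arrays as a block, with replicates 1 and 2 or 3 and 4 alone, with all 12 arrays as separate samples and with the averaged array as number 2 of the replicate block were chosen only after the data were seen. Counts below are in the order lower and higher against the daf-12 mutant, lower and higher against wild type. With array weights they were 989, 1346, 164 and 216, with 141 lower and 173 higher than both groups and 43 and 30 ciliary genes called. With replicates 3 and 4 alone they were 1050, 841, 130 and 67, with 111 lower and 51 higher than both, 42 and 22 ciliary genes, and 13 higher in the daf-12 mutant than in wild type. With replicates 1 and 2 alone limma called 0 lower and 0 higher in each comparison, and 0 ciliary genes, with 11 lists past the threshold against the daf-12 mutant; fewer arrays account for part of this. With all 12 arrays as separate samples 30 were lower and 1 higher against the daf-12 mutant, and 39 of 43 calls against wild type were lower. This came with 27 lower and 1 higher than both and 13 and 16 ciliary genes. A block for the set of arrays gave 41, 7, 44 and 7, with 36 and 4 in both, 12 and 16 ciliary genes and 5 higher in the daf-12 mutant.

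With a replicate block 2 were higher against the daf-12 mutant, 5 higher against wild type and 2 higher than both; with the averaged array as number 2 of the block, 2 and 2 were higher and 0 in the daf-12 mutant against wild type. With only 2 groups in the fit, 8 were lower against the daf-12 mutant, 0 higher against wild type, 0 higher in the daf-12 mutant, 5 lower than both, and 2 ciliary genes called. Quantile normalization gave 1 higher against the daf-12 mutant. At an adjusted p under 0.01, which is stricter by construction, 3 and 12 were lower and 0 higher against the daf-12 mutant and wild type, 0 in the daf-12 mutant, 3 lower than both, and 1 and 6 ciliary genes called. An estimated correlation left 4, 5 and 1 lists past the threshold in the 3 comparisons. Apart from those with fewer arrays or a stricter bound, the cause was not tested.

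Leaving out 1 array at a time gave 1 to 26 lower and 0 to 48 higher against the daf-12 mutant, 2 to 27 lower and 0 to 14 higher against wild type, and 0 to 2 higher in the daf-12 mutant. It gave 1 to 21 lower and 0 to 12 higher than both, and 1 to 12 and 1 to 14 ciliary genes called. Lists past the threshold ranged from 16 to 22, 12 to 18 and 8 to 15; the lowest, 8, came without daf-12 array 3 or wild type array 3. The adjusted p of daf-19 against the daf-12 mutant ranged from 0.0178 to 0.279, and its call held in 4 of 11 such fits; Y41E3.5, R102.2, dylt-2 and xbx-3 held in 7, 9, 6 and 7, and mksr-2, tmem-107, bbs-5 and xbx-9 in 4, 5, 3 and 5. The call of nhj-1 held in 9 of 11 fits against wild type in the double mutant and in 1 of 11 in the daf-12 mutant.

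The direction of a list here is that of camera, which sets the list against all other genes. Nuclear hormone receptors could thus reverse while their medians within replicates 1 and 2 kept their sign. In replicates 1 and 2 the double mutant had 1 different array, assumed to vary like the other groups. P-values from that set rest on the spread of the other groups. The following directions reversed with replicates 1 and 2 alone. Against the daf-12 mutant these were the lists of receptor guanylyl cyclases (adjusted p = 0.591), major sperm proteins (4.2e-05), DNA replication (0.405), histones (0.000141) and nuclear hormone receptors (0.582), and the gene daf-12, at 0.30. Against wild type they were chemoreceptors (0.0215), DNA replication (0.224) and histones (0.0293). For the daf-12 mutant against wild type they were chemoreceptors (0.0785), early embryo (0.307), major sperm proteins (0.119), histones (0.105) and nuclear hormone receptors (0.814). There, replicates 3 and 4 alone reversed the transition zone (0.60) and collagen lists (0.0688). Chemoreceptors reversed without daf-12 array 3 (0.874), daf-12 array 4 (0.884) or wild type array 1 (0.371), and neuropeptides without wild type array 1 (0.212). Over all single arrays left out, the adjusted p ranged from 2.2e-07 to 0.884 for chemoreceptors and from 7.2e-08 to 0.381 for neuropeptides. The cause was not tested.

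Of 67 values of named genes, 48 kept their direction and side of the threshold with a replicate block, 13 gained a call and 6 lost it. With the set of arrays as a block 35 kept both and 32 gained a call. The 67 included values taken because that block called them, so these 32 gains were fixed by the choice and test nothing. Of 45 list results past the threshold, 43 kept both with a replicate block and 10 with an estimated correlation. The X-box motif test was not run. Signal over background limits the dim probe sets, and leaving them out kept 59 of the 67 and 41 of the 45.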

Other observations

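The comparison of the 2 sets of arrays was chosen only after the spike-in values were seen. With the genotype in the model, 3083 probe sets were lower and 2449 higher in replicates 3 and 4 than in replicates 1 and 2 (limma, adjusted p under 0.05). Cuticle collagens and neuropeptides were among the higher lists: 60 of 128 collagen genes were called higher and 3 lower (median 0.55, camera adjusted p = 2.3e-14), and 31 of 83 neuropeptide genes were called higher and 1 lower (median 0.56, adjusted p = 2.1e-09). Chemoreceptor genes were lower, with 424 of 1275 called lower and 4 higher (median -0.33, adjusted p = 1.7e-18), as were early embryo genes, with 7 of 24 called lower (median -0.35, adjusted p = 0.00691). IFT complex B (13 genes, median 0.47, camera adjusted p = 0.0145) and furrow collagens (17, 0.34, 0.0238) were higher too. The rest of the 6 ciliary lists pointed up without passing, at camera adjusted p of 0.261 to 0.491. The rise of complex B lay mostly in the daf-12 mutant, whose arrays 1 to 4 had list means of -0.49, -0.23, 0.98 and 1.29. Wild type arrays 1 to 4 had -0.05, 0.54, -0.08 and 0.60, and double mutant arrays 1-2, 3 and 4 had -0.93, -0.82 and -0.80. With an estimated correlation each list that passed had an adjusted p = 0.834. Among single genes, rrn-3.56, a ribosomal RNA gene, differed by 4.94 ± 0.31 (SE), rrn-3.1 by 3.75 ± 0.66 and egl-30, a G protein subunit gene, by -3.72 ± 0.17. The gene R11A5.3, higher in the double mutant with the set of arrays as a block, also differed between the sets, by 2.17 ± 0.16.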
